A study of Mus musculus with 14 samples.

How the data were processed

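The 14 samples were peritoneal cells of female C57Bl/6 x C3H F1 mice, 12 to 16 weeks old and housed 5 per cage, in 5 groups that were taken from the sample titles. There were 2 naive arrays and 3 each for LPS, and for LPS after SMD at 100, 200 or 300 mg/kg. Per the labels' protocols, SMD was applied to the nares in a volume of 50 µl under halothane, RNA was isolated with Trizol, and about 7.5 µg of total RNA was labelled with the one-cycle kit of the array's maker. One treatment text is attached to all samples, naive ones included, so it does not tell what the controls received.

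The deposited values are the authors' intensity per probe set on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 reduces the perfect-match and mismatch probes of a probe set to 1 signal and scales each array. In the deposited values the mean left after trimming 2% of probe sets at each end was 500 on all 14 arrays, and there were 0 negative values. Detection calls were not used here. A scaled signal shows changes relative to the rest of the array, so a shift of most transcripts in one direction would appear as an opposite shift of the others.

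Each array held 45101 probe sets. The 64 control probe sets were left out, except for the 3'/5' ratios of actin and Gapdh, which left 45037. The platform annotation gave 34945 of these a single gene symbol, 932 several and 9160 none. Of the 34945 symbols, 34741 were brought up to date through their Entrez identifiers with RefSeq gene tables of assembly GRCm38.p6 and 204 were kept as given. Probe sets with several symbols were never named. No coordinates are reported.

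Values were transformed as log2(signal + 16) with no further scaling, and the 40% of probe sets with the lowest mean were left out (a mean log2 value under 5.64, about a signal of 33.9). This left 27022 probe sets for 12817 genes. The pseudocount makes changes of dim genes appear smaller than they are. A linear model with 1 mean per group was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with moderated variances that follow the intensity, two-sided tests and Benjamini-Hochberg adjustment over all 27022 probe sets. A probe set was called at an adjusted p under 0.05. Naive was compared with LPS, each SMD dose with LPS, and the doses with each other. The dose trend was a linear term over the 12 arrays of LPS-challenged mice. Errors of log2 changes are limma's standard errors.

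A total of 27 gene lists, 17 pathways and 10 sets of cell markers, were tested. The pathway lists were inflammatory cytokines, chemokines, anti-inflammatory regulators, interferon-stimulated genes, TLR4 pathway components, NF-kB family, MAP kinases with phosphatases and AP-1, NRF2 and thiol response, metal and heat-shock response, unfolded protein and ATF4 response, glucocorticoid response, antimicrobial effectors, prostaglandin enzymes, antigen presentation, apoptosis, cell cycle and cholesterol. Markers covered resident macrophages, neutrophils, B cells, T and NK cells, mast cells, eosinophils, monocytes and dendritic cells, mesothelial cells and fibroblasts, red cells and platelets. 1 probe set stood for a gene, the one with the highest mean. Lists were tested with limma's camera, with a preset correlation of 0.01 and with one estimated from the data, and with fry, adjusted over the 27 lists. Camera with the preset correlation called 16 lists in LPS against naive and 3, 5 and 3 at 100, 200 and 300 mg/kg against LPS, and with an estimated correlation 10, 0, 0 and 0 of them held. With single arrays left out the preset correlation called 2 to 5, 3 to 6 and 2 to 6 at the 3 doses. The 2 at 100 mg/kg came without 100 mg/kg replicate 3 and the 5 without LPS replicate 1, 100 mg/kg replicate 1 or 300 mg/kg replicate 3. The 3 at 200 mg/kg came without LPS replicate 3 or 200 mg/kg replicate 3. The highest numbers at 300 mg/kg were 6 without 300 mg/kg replicate 3 and 5 without LPS replicate 1. The other settings chosen beforehand called 2 to 5, 3 to 6 and 2 to 5 lists. Fry tests whether the genes of a list move, on balance, in one direction, without comparing them with other genes, and called 23, 0, 1 and 17.

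The groups, tests, lists, the other settings named next and the rule for named genes were set before the data were examined. The rule named 12 genes in every comparison (Tnf, Il1b, Il6, Il10, Il12b, Nos2, Ptgs2, Cxcl10, Ifnb1, Cd14, Tlr4 and Hmox1). It added the 5 largest called increases and 5 largest called decreases whose arrays did not overlap between groups and whose level in the higher group was at or above the median, and up to 4 members per list with the smallest p. Where nothing was called, it took the 3 largest changes each way at small unadjusted p. Genes outside the rule, such as the macrophage markers Adgre1, Csf1r, Cd68, Lyz2, Vsig4 and Timd4 and single genes in the closing observations, were chosen after their values were seen. Where a gene had several probe sets, the one with the highest mean is given. Of 5704 genes with several tested probe sets, 70 had probe sets called in opposite directions in LPS against naive, 0, 69 and 190 at 100, 200 and 300 mg/kg against LPS and 197 in the dose trend.

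The other settings, chosen then too, were a pseudocount of 1 or 64, no filter or the lowest 60% left out, quantile normalization, median scaling, only the compared groups in the fit, no intensity trend, array weights, the replicate number as a block, 1 averaged value per gene, and leaving out each array in turn. After the data were seen, the log2 actin or Gapdh 3'/5' ratio as a covariate and a fit restricted to arrays with an actin ratio from 4 to 12 were added. That fit kept 1 LPS array (replicate 2), 2 at 100, 3 at 200 and 1 at 300 mg/kg (replicate 1). Its single arrays were assumed to vary like the 100 and 200 mg/kg groups. Where leaving out an array left a single naive array, that array was assumed to vary like the other groups.

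The code was tested on simulated data with the real means and 27022 probe sets, of which 100 were changed by 1 and 100 by 2 log2 units per comparison. It recovered 18% of the former and 61% of the latter in LPS against naive, with 9 false calls, and 24% and 57%, 27% and 70%, and 24% and 57% at 100, 200 and 300 mg/kg against LPS, with 8, 5 and 2 false calls. In each comparison the 1 shifted list was called and 0 others. The simulated genes varied independently, so false list calls that come from correlated genes could not arise in this test. No arrays were duplicates, since at most 0.266% of values were identical in any of 91 pairs.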

Results

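Transcript levels were measured on 14 mouse expression arrays with 45101 probe sets each. The total RNA came from peritoneal cells, which the sample labels call macrophages, of female C57Bl/6 x C3H F1 mice. 2 arrays came from naive mice and 3 from mice challenged with lipopolysaccharide (LPS), the outer-membrane glycolipid of Gram-negative bacteria, injected into a vein at 60 µg per mouse. A further 3 arrays each came from mice that received SMD at 100, 200 or 300 mg/kg on the nares 30 min before the same LPS dose. The labels do not spell out SMD. Cells of the SMD groups were taken 2.0 h after LPS, and the harvest time of the LPS group is not stated. Nor is it stated whether the LPS and naive mice received a vehicle in place of SMD. The labels call the arrays of LPS-challenged mice biological replicates and the naive arrays replicates, without saying whether 1 mouse or a pool stands behind each. The p-values therefore measure only the spread between these samples, which may be technical for the naive arrays and may lie between pools for all. The median signal of an array lay between 65.1 and 84.8, and the number of arrays limits the precision. Pearson's r across the tested probe sets, which are not independent replicates, was 0.925 to 0.954 within groups and 0.839 to 0.950 between groups.

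The 3'/5' ratio of the beta-actin control probe sets, a measure of how much of each transcript's length reached the array, differed between arrays. It was 2.94 ± 0.146 in naive mice (mean ± SD, n = 2), 3.32 ± 2.21 after LPS, 6.21 ± 4.73 at 100 mg/kg SMD, 9.81 ± 0.864 at 200 mg/kg and 14 ± 6.24 at 300 mg/kg (n = 3 each). The Gapdh ratio was 7.82 ± 1.48, 37.8 ± 47.4, 41.7 ± 28.5, 89.1 ± 23.9 and 92.0 ± 76.9 in the same order. Against LPS alone, exact two-sided permutation tests of the log2 actin ratio gave p = 0.4, 0.1 and 0.1 for the 3 doses, or 0.4, 0.15 and 0.15 after Benjamini-Hochberg adjustment over the 3 tests. The smallest p that 3 arrays against 3 allow is 0.1. Across the 12 arrays of LPS-challenged mice, the log2 actin ratio correlated with the SMD dose (Pearson's r = 0.78, two-sided permutation p = 0.00363, Spearman's rho = 0.756, permutation p = 0.00713, 1 relation tested). Of the 6 arrays equally far from the median dose, the 2 with the most extreme ratios were left out, and r was then 0.628. Neither scan dates nor batches are given in the labels.

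**Figure D1:**
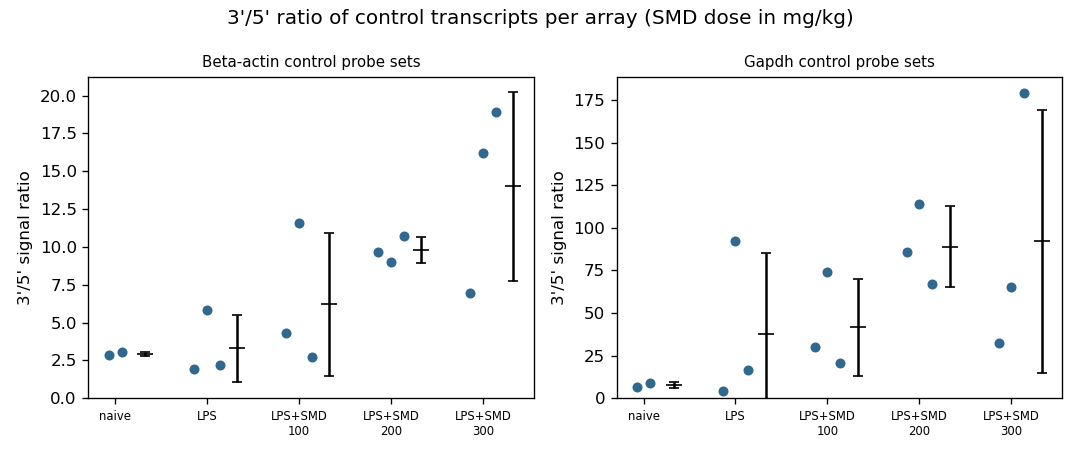
The 3'/5' signal ratio of the actin and Gapdh control probe sets is plotted for each array (points) by group, with the mean and SD as bars. The actin ratio averaged 3.32 after LPS alone and 14 at 300 mg/kg SMD, and the lower end of the Gapdh SD bar of the LPS group lies below 0 and is not drawn.

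The comparison of LPS with naive mice asked how the challenge changed expression in the peritoneal cells. The transcripts of chemokines, cytokines and interferon-stimulated genes rose. The largest increases were those of Cxcl10, a chemokine that attracts T cells, at a log2 change of 9.82 ± 0.29 (SE, n = 3 and 2, limma adjusted p = 2.61e-14), and of Acod1, the enzyme that makes itaconate, at 9.33 ± 0.42. Others were the chemokines Ccl3 (8.97 ± 0.21) and Cxcl11 (8.61 ± 0.45) and the acute-phase gene Saa1 (8.43 ± 0.52). The naive signals of Cxcl10, Ccl3, Cxcl11 and Saa1 averaged 24.6, 15.6, 4.65 and 12.5, under the level of 33.9 below which probe sets were not tested, and the 2 of Acod1 averaged 51.9 ± 66.7 (SD). The sizes, and the order after Cxcl10, therefore depend on the pseudocount. Cxcl10 stood at 10.71 with a pseudocount of 1 and 8.60 with 64, and Cxcl11 at 10.60, above Acod1 (10.36), and 6.88, below Saa1 (6.95). The largest decreases were those of Marveld1 (-5.40 ± 0.48, adjusted p = 1.37e-07), the Rac activator Tiam2 (-4.85 ± 0.63), the histamine-degrading enzyme Hnmt (-4.61 ± 0.64), Mdm1 (-4.56 ± 0.56) and Cyp26a1, which degrades retinoic acid (-4.49 ± 0.70). For these 10 genes all 3 LPS arrays lay on the same side of both naive arrays. Among genes with a role in endotoxin responses, Tnf (4.18), Il1b (5.98), Il6 (3.90 ± 0.34), Il10 (3.67 ± 0.31) and Cd14 (2.45) rose. Tlr4, the LPS receptor, fell by 1.45 ± 0.44 (adjusted p = 0.0196), a call lost after median scaling (-1.02, adjusted p = 0.121) and without LPS replicate 3 (-0.99, 0.101) or either naive replicate (0.132 and 0.0824). Il12b rose by 2.03 ± 0.68 (adjusted p = 0.0317), but not without naive replicate 2 (1.39, adjusted p = 0.298), LPS replicate 1 (1.88, 0.0879) or LPS replicate 2 (1.94, 0.0762). Ifnb1 (-0.28 ± 0.57, adjusted p = 0.776) and Hmox1 (0.46 ± 0.41, adjusted p = 0.457) did not pass the test. Nos2 was too dim to be tested, with signals of 3.1 to 41.9.

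Of 19 measured inflammatory cytokines 14 rose and none fell (15 and 0 adjusted over the list alone), among them Tnfsf9 (6.24) and Il1a (4.82). Chemokines rose in 19 of 21 (19 adjusted over the list alone), with Ccl4 at 6.38 and the neutrophil attractant Cxcl1 at 5.60. All 36 measured interferon-stimulated genes rose (36 adjusted over the list alone), including the antiviral genes Ifit1 (7.36), Rsad2 (7.29) and Oasl1 (7.05), with a median of 3.37. Their camera adjusted p was 6.07e-28 with the preset correlation, and the call was lost at an adjusted p = 0.0598 with an estimated correlation. That correlation was estimated from the residuals of all 14 arrays. The mean of these genes varied most at 300 mg/kg SMD (SD 1.19, against 0.07 in naive mice and 0.10 after LPS). The loss therefore need not come from the 2 groups compared. Of 15 NF-kB family members and inhibitors 14 rose (14 adjusted over the list alone), such as Tnfaip3 (4.53) and Bcl3 (3.12), both brakes on NF-kB signalling. Of 17 anti-inflammatory regulators 14 rose and none fell (14 and 0 adjusted over the list alone), including the interleukin-1 receptor antagonist Il1rn (7.06) and Socs3 (3.13). TLR4 pathway components rose in 9 of 22 and fell in 3 (the same numbers adjusted over the list alone), with Tlr2 (2.72) and Myd88 (2.62) among those that rose. Without naive replicate 1 or 2, 1 of them fell, and without naive replicate 2, 6 rose. Of 28 MAP kinases, dual-specificity phosphatases and AP-1 members 16 rose and 3 fell (18 and 4 adjusted over the list alone), including Map3k8 (3.18) and the phosphatase Dusp16 (3.12). Camera called the cytokines (adjusted p = 3.76e-11), chemokines (3.65e-22), NF-kB members (8.18e-16), anti-inflammatory regulators (7.31e-17), TLR4 components (0.00204) and MAP kinase list (2.4e-07) upward. These 6 calls held with an estimated correlation.

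The unfolded protein and ATF4 list rose in 15 of 24 members and fell in 2 (16 and 2 adjusted over the list alone, camera adjusted p = 9.12e-08), with the amino acid transporter Slc7a5 at 4.45 and asparagine synthetase Asns at 2.98. None of these fell without LPS replicate 1 or either naive replicate, and 1 fell without LPS replicate 3 or 200 mg/kg replicate 1. Of 23 glucocorticoid-response genes 11 rose and 6 fell (12 and 6 adjusted over the list alone, 0.000182), such as the iron-siderophore carrier Lcn2 (7.71) and transglutaminase Tgm2 (5.29). Among 21 apoptosis regulators 10 rose and 3 fell (11 and 3 adjusted over the list alone, 0.00119), such as the caspase-8 inhibitor Cflar (2.91) and the death receptor Fas (2.56). These 3 calls also held with an estimated correlation. The NRF2 and thiol stress response list rose in 7 of 25 members (7 adjusted over the list alone, camera adjusted p = 0.0139), led by the cystine transporter Slc7a11 (5.07) and Txnrd1 (2.72). That call was lost at an adjusted p = 0.0937 with an estimated correlation and at 0.0513 after quantile normalization. Metal and heat-shock genes rose in 8 of 15 and fell in 1 (9 and 1 adjusted over the list alone, 2.53e-05, adjusted p = 0.0924 with an estimated correlation), including the metallothioneins Mt2 (6.63) and Mt1 (3.89). Without naive replicates 1 and 2 those that rose numbered 4 and 5. Antimicrobial effectors rose in 9 of 21 and fell in 2 (11 and 2 adjusted over the list alone, 1.05e-06, adjusted p = 0.0585 with an estimated correlation), including Sod2 (3.13) and Gch1 (3.20). Of the antimicrobial list 1 fell without LPS replicate 2 or naive replicate 1 and none without naive replicate 2. Antigen presentation and costimulation genes rose in 8 of 19 (9 adjusted over the list alone, 5.69e-05, adjusted p = 0.111 with an estimated correlation), including the adhesion molecule Icam1 (3.40) and Cd86 (2.09). Cell cycle genes fell in 11 of 20 (14 adjusted over the list alone, 0.00255, adjusted p = 0.263 with an estimated correlation), such as Top2a (-2.33) and Rrm2 (-2.14). The cell cycle genes that fell numbered 7 without naive replicate 1, 4 without naive replicate 2 and 7 without LPS replicate 2. Prostaglandin and leukotriene enzymes went both ways, with 5 of 16 up and 7 down (5 and 8 adjusted over the list alone). Their median was -0.40 (0.03 after median scaling) and their mean 0.48, while Ptgs2 (6.43) and Ptges (5.75), the inducible enzymes of prostaglandin E2 synthesis, rose. Without naive replicate 1 or 2, 3 of the prostaglandin list fell, and without LPS replicate 2 it was 4. Cholesterol genes rose in 2 of 19 and fell in 3 (3 and 5 adjusted over the list alone, camera adjusted p = 0.913, median -0.33, which was 0.10 after median scaling). They rose in 1 without LPS replicate 2 or 3, 100 mg/kg replicate 1 or 2, 200 mg/kg replicate 1 or 2, or either naive replicate, and fell in 1 without LPS replicate 1 or either naive replicate.

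Markers of other cell types changed too, which need not mean a change in the number of those cells. The neutrophil list also shares Lcn2 with the glucocorticoid and antimicrobial lists. Of 15 neutrophil markers 9 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 4.58e-07, held with an estimated correlation), with S100a9 at 3.88 and S100a8 at 3.63. Without LPS replicate 3, 2 of them fell. Of 23 resident peritoneal macrophage markers 4 rose, such as Fcgr1 (3.42), and 9 fell, such as Garnl3 (-2.53), with the same numbers adjusted over the list alone and a median of -0.16 that was 0.27 after median scaling. Without naive replicate 2, 5 of them fell. B cell markers fell in 6 of 16 (7 adjusted over the list alone, median -0.48), with Cr2 at -2.06. After median scaling 2 rose and 4 fell, and without naive replicate 1 or 2 it was 3 that fell. T and NK markers rose in 2 of 18 and fell in 4 (2 and 5 adjusted over the list alone), among them Gzmb (5.15) and Thy1 (-2.11), with 1 that rose without naive replicate 1. Numbers up and down were 3 and 2 of 11 mast cell, 0 and 2 of 4 eosinophil, 3 and 3 of 11 monocyte and dendritic cell, 1 and 0 of 13 mesothelial and fibroblast, 2 and 0 of 6 red cell and 2 and 0 of 9 platelet markers, and were the same adjusted over the list alone. Without naive replicate 2, 1 mast cell marker fell and 1 monocyte and dendritic cell marker rose. Eosinophil markers fell in 1 without any 1 of the LPS replicates and in 0 without either naive replicate. Red cell markers rose in 1 without LPS replicate 2 or 200 mg/kg replicate 2 and in 0 without LPS replicate 3 or either naive replicate. Platelet markers rose in 1 without LPS replicate 2 or 3 or naive replicate 2 and in 0 without naive replicate 1. Camera called neither these nor the macrophage, B and T cell lists, but after quantile normalization it called the resident peritoneal macrophage markers (adjusted p = 0.0153) and the B cell markers (0.00512) downward. Across all probe sets limma called 7313 of 27022, of which 2773 were higher and 4540 lower, for 4164 genes. Without naive replicate 1 the count was 4397 and without naive replicate 2 it was 4362. The split depended on scaling. The share of calls that were higher was 37.9%, against 48.1% after quantile normalization and 68.1% after median scaling, while the median change of all probe sets moved from -0.25 to -0.07 and 0.18.

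The comparison of SMD at 100 mg/kg with LPS alone asked what the lowest dose added. No gene passed the test. The largest differences at small unadjusted p were those of Srxn1, a gene of the oxidant response that reduces peroxiredoxins, at 1.91 ± 0.39 (SE, n = 3 each, limma adjusted p = 0.225), Apba1 (1.69 ± 0.34, 0.225) and Dennd5b (1.53 ± 0.34, 0.262). In the other direction stood Fbxo42 (-1.74 ± 0.43, 0.301), Clec2d (-1.64 ± 0.35, 0.246) and Irf4 (-1.50 ± 0.34, 0.267). In these 6 genes the 3 arrays of one group all lay beyond those of the other. Il6 stood at 0.94 ± 0.31 (adjusted p = 0.423), Tnf at 0.56 ± 0.28 (0.57) and Cxcl10 at -0.07. Limma called 0 probe sets, with 2428 at an unadjusted p under 0.05 against 1351 that chance gives and a smallest adjusted p of 0.193. Without 100 mg/kg replicate 3 it called 470, among them Il6 (1.51, adjusted p = 0.00074), Srxn1 (1.66, 0.0499), Apba1 (1.91, 0.0193), Dennd5b (1.83, 0.0186), Clec2d (-1.56, 0.0499), Fbxo42 (-2.06, 0.031) and Irf4 (-1.88, 0.0148). No list member was called over all probe sets. Adjusted over the list alone, 4 cell cycle genes, 3 heat-shock genes, 2 NRF2 genes, 2 B cell markers and 1 each of the cytokines, MAP kinase members and prostaglandin enzymes were higher. Of the glucocorticoid genes 2 were higher and 3 lower, and of the monocyte and dendritic cell markers 1 was higher and 2 lower. Camera placed the cell cycle list (median 0.73, adjusted p = 0.000133) and the NRF2 and thiol stress response list (median 0.26, 0.00639) upward and the unfolded protein and ATF4 list (median -0.20, 0.000698) downward. With an estimated correlation the adjusted p values were 0.555, 0.458 and 0.543. The NRF2 call was also lost without LPS replicate 2 (0.0784) and without 100 mg/kg replicate 3 (0.113), with array weights (0.0586) and with 1 value per gene (0.0961).

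At 200 mg/kg, the comparison with LPS alone showed higher transcripts of Il6, of 7 of 25 NRF2 and thiol genes and of 5 of 15 metal and heat-shock genes, and lower transcripts of 10 of 36 interferon-stimulated genes. The largest increases were those of Pxdc1 (log2 change 3.23 ± 0.44, SE, n = 3 each, limma adjusted p = 0.000373), the small heat-shock protein gene Hspb1 (3.18 ± 0.46, 5e-04), Mid1 (3.17 ± 0.96, 0.0372), Srxn1 (2.73 ± 0.39, 0.000483) and the transcription factor Nfia (2.65 ± 0.43, 0.00107). The largest decreases were those of Cdca7 (-3.79 ± 0.57, 0.000612), Triobp (-3.34 ± 0.72), the AP-1 member Junb (-3.31 ± 0.58), the antiviral helicase Znfx1 (-2.84 ± 0.70, 0.0135) and Id1 (-2.81 ± 0.55). In these 10 genes the arrays of the groups did not overlap. Il6 rose by 2.10 ± 0.31 (0.000543). Tnf (0.54 ± 0.28, 0.23), Il1b (0.23, 0.513), Il10 (0.44, 0.322), Ptgs2 (0.78, 0.0643), Cxcl10 (-0.33, 0.455), Ifnb1 (1.26 ± 0.51, 0.115), Cd14 (-0.24, 0.131) and Hmox1 (0.92 ± 0.36, 0.105) did not pass, nor did Tlr4 (0.52) and Il12b (-0.85). Single arrays decided some of these: Il10 passed without 200 mg/kg replicate 3 (0.82, 0.0437), Hmox1 without 100 mg/kg replicate 1 (0.049) or 3 (0.0328), and Ptgs2 without 100 mg/kg replicate 3 (0.0286) or naive replicate 1 (0.0459) or 2 (0.0455). The actin 3'/5' ratio was 9.81 in this group against 3.32 after LPS. With the ratio as a covariate, Pxdc1, Hspb1, Srxn1, Il6, Gclm, Abcc1, Slc30a1, Rel, Arg1, Fcgr1, Pmaip1 and Ptges kept their calls, while Mid1, Nfia, Cdca7, Triobp, Junb, Znfx1 and Id1 lost theirs at unchanged signs. Mid1 was no longer called without LPS replicate 2 (adjusted p = 0.0653), LPS replicate 3 (0.207) or any of 200 mg/kg replicates 1 (0.102), 2 (0.0977) and 3 (0.0635), and Znfx1 without LPS replicate 1 (0.0783) or 3 (0.0616).

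Interferon-stimulated genes fell in 10 of 36 members and rose in none (13 and 0 adjusted over the list alone), with a median of -0.68. Examples were the antiviral genes Oas3 (-2.26 ± 0.36, adjusted p = 0.000862) and Bst2 (-1.85 ± 0.28, 0.000662). Camera called the list downward (adjusted p = 4e-07), a call lost at an adjusted p = 0.6 with an estimated correlation. With the actin ratio as a covariate no member was called, at a median of -0.78. The number called was 3 without LPS replicate 1 or 3 and 6 without 200 mg/kg replicate 1 or 2, and ranged from 3 to 15 over the arrays left out. The fit gave each probe set 1 spread shared by all groups. The mean of the 36 genes varied most at 300 mg/kg (SD 1.19, against 0.10 after LPS and 0.21 at 200 mg/kg). That group's spread enters the errors here, so the count does not rest on the 2 compared groups alone. NRF2 and thiol genes rose in 7 of 25 and fell in 1 (7 and 1 adjusted over the list alone, median 0.39). Among them were Gclm, a subunit of the enzyme that starts glutathione synthesis (2.10 ± 0.31, 0.000556), the glutathione exporter Abcc1 (1.28 ± 0.26), Slc7a11 (1.71), catalase Cat (0.79) and glutathione reductase Gsr (0.75). The camera adjusted p was 0.0048 and became an adjusted p = 0.41 with an estimated correlation, while fry gave 0.00368. With the actin covariate 4 members were called higher. The metal response and heat shock list rose in 5 of 15 members (8 up and 1 down adjusted over the list alone, camera adjusted p = 0.0496, adjusted p = 0.6 with an estimated correlation), such as the zinc exporter Slc30a1 (1.66 ± 0.24) and the chaperone Hsph1 (1.72). With the actin covariate 2 members were called, Hsph1 not among them. The list's call was lost without LPS replicate 1 (0.0515), 2 (0.0588) or 3 (0.107), 100 mg/kg replicate 1 (0.0594) or 3 (0.0533), 200 mg/kg replicate 3 (0.244) or either naive replicate (0.0533 and 0.0531). It was also lost with a pseudocount of 1 (0.0553), the lowest 60% left out (0.139), quantile normalization (0.0902), no intensity trend (0.127), array weights (0.12), the replicate block (0.0682) and the actin (0.553) or Gapdh (0.0836) covariate. The unfolded protein and ATF4 list fell in 6 of 24 (1 up and 7 down adjusted over the list alone, 0.0048, adjusted p = 0.6 with an estimated correlation), such as Ddit4 (-1.92) and Slc7a5 (-1.99). With the actin covariate none of them was called and the list's call was lost (0.0772), and without LPS replicate 1 or 3 it was 3 that fell. Slc7a5 was not called without LPS replicate 1 (adjusted p = 0.0515) or LPS replicate 3 (0.0585). The antigen presentation and costimulation list rose in 1 of 19 members and fell in 5 (2 and 7 adjusted over the list alone, 0.031, adjusted p = 0.6 with an estimated correlation), including the immunoproteasome subunits Psmb8 (-1.12) and Psmb9 (-1.28), both not called with the actin covariate. Without LPS replicate 1 or 3, 3 members fell, and without LPS replicate 3 or 100 mg/kg replicate 3, 2 rose. This list's call was lost after median scaling (0.0552), without LPS replicate 3 (0.141) and without 200 mg/kg replicate 3 (0.18). The lowest 60% left out (0.0504), no intensity trend (0.0686) and the actin (0.557, median 0.01) or Gapdh (0.0836) covariate ended it too.

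The other lists were not called by camera at 200 mg/kg. Cytokines rose in 3 of 19 and fell in 4 (3 and 5 adjusted over the list alone), chemokines fell in 2 of 21 (2 adjusted over the list alone) and anti-inflammatory regulators fell in 5 of 17 (6 adjusted over the list alone). Of 15 NF-kB members 2 rose, such as the subunit Rel (1.57 ± 0.22), and 3 fell (3 and 8 adjusted over the list alone). Apoptosis regulators rose in 5 of 21 and fell in 2 (6 and 2 adjusted over the list alone), with the pro-apoptotic Pmaip1 at 1.55 ± 0.25. These counts rested on single arrays. Without LPS replicate 1, 200 mg/kg replicate 1, 2 or 3 or LPS replicate 3, the anti-inflammatory regulators that fell numbered 1, 3, 3, 2 and 2 in that order, and the NF-kB members 1, 1, 1, 2 and 1, or 7 without LPS replicate 2 and 6 without 100 mg/kg replicate 3. No cytokine fell without LPS replicate 1 or 3 and 2 did without 200 mg/kg replicate 1 or 3, while 1 rose without LPS replicate 3 or 200 mg/kg replicate 1. The chemokines that fell numbered 1 without LPS replicate 1 and 0 without LPS replicate 3 or any 200 mg/kg array. Without any 1 of LPS replicates 1 and 3, the 200 mg/kg arrays and the naive arrays, 3 apoptosis regulators and 1 NF-kB member rose. Without any 1 of the LPS arrays or 200 mg/kg replicate 1, 1 apoptosis regulator fell, and without 200 mg/kg replicate 3, 1 anti-inflammatory regulator rose. Among single genes of the remaining lists, arginase Arg1 rose by 1.76 ± 0.30 and the prostaglandin synthase Ptges fell by 1.54 ± 0.28. The high-affinity IgG receptor Fcgr1 fell by 2.06 ± 0.32, while 1 of 23 macrophage markers rose and 2 fell (1 and 3 adjusted over the list alone, median 0.01). T and NK markers rose in 5 of 18 and fell in 2 (6 and 2 adjusted over the list alone), with the costimulatory receptor Cd28 at 2.39, a call lost with the actin covariate. The T and NK markers that rose numbered 2 without LPS replicate 1 and 3 without LPS replicate 3 or any 200 mg/kg array. Those that fell numbered 0 without LPS replicate 1 or 3 or 200 mg/kg replicate 1 or 2, and 1 without 200 mg/kg replicate 3. The macrophage markers that fell numbered 1 without LPS replicate 1 or 3, 100 mg/kg replicate 1, any 200 mg/kg array or either naive array. Those that rose numbered 0 without LPS replicate 3 or 200 mg/kg replicate 1 or 2, and 2 without 200 mg/kg replicate 3. Limma called 3532 probe sets, 1804 higher and 1728 lower, for 1916 genes. After median scaling 64.1% of calls were higher, against 51.1%, and the median of all probe sets moved from -0.05 to 0.10. The count was 407 with the actin covariate and 743 with the Gapdh covariate. It was 1264 without LPS replicate 1, 1554 without LPS replicate 3, and 2085, 2280 and 2264 without 200 mg/kg replicates 1, 2 and 3.

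At 300 mg/kg, the comparison with LPS alone showed lower transcripts of all measured interferon-stimulated genes and higher Il6 and Ifnb1. The largest decreases were those of Znfx1 (log2 change -5.21 ± 0.70, SE, n = 3 each, limma adjusted p = 2.64e-05) and of the interferon-inducible genes Iigp1 (-4.65 ± 0.58), Slfn5 (-4.58 ± 0.47, 2.29e-06), Usp18 (-4.55 ± 0.78) and Ifit3 (-4.37 ± 0.79, 0.000395). The largest increases were those of Marveld1 (4.19 ± 0.43, 2.01e-06), the linker histone gene H1f2 (4.09 ± 0.27, 7.76e-08), Mdm1 (3.99 ± 0.50), the growth-arrest gene Gadd45a (3.82 ± 0.30, 2.86e-07) and Pxdc1 (3.79 ± 0.44). In each of the 10 the 3 arrays of one group lay beyond those of the other. Il6 rose by 2.80 ± 0.31 (4.03e-06) and Ifnb1, which encodes interferon beta, by 3.24 ± 0.51 (0.000122). After LPS alone Ifnb1 stood at a log2 value of 5.90, near its naive level of 6.18 and the filter cut of 5.64. The size of its rise therefore depends on the pseudocount. Il10 rose by 1.13 ± 0.28 (0.00458) and Ptgs2 by 1.25 ± 0.27 (0.00191), and Cxcl10 (-1.26 ± 0.26, 0.00126) and Cd14 (-0.41 ± 0.10, 0.00556) fell. Tnf (-0.23 ± 0.28, 0.605), Il1b (-0.35 ± 0.21, 0.24), Il12b (-0.95, 0.277), Tlr4 (-0.27, 0.668) and Hmox1 (0.85 ± 0.36, 0.0922) did not pass. The actin ratio was 14 in this group against 3.32 after LPS. With it as a covariate Il10 (0.84, adjusted p = 0.196), Ptgs2 (0.77, 0.208) and Cd14 (-0.40, 0.074) lost their calls, and Tlr4 was called lower (-1.59, 0.0183). Cd14 also lost its call after median scaling (-0.31, 0.154), and Ptgs2 when its probe sets were averaged (0.27, adjusted p = 0.614). Hmox1 passed without 100 mg/kg replicate 1 (0.0384) or 3 (0.0281) and without 300 mg/kg replicate 2 (1.18, 0.0373).

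Interferon-stimulated genes fell in 36 of 36 members (36 adjusted over the list alone), with a median of -2.77. Oas3 stood at -3.93 ± 0.36 (adjusted p = 8.07e-07), Isg20 at -3.93, Oas2 at -3.09 and Bst2 at -2.77. The mean log2 signal of the 36 genes was 9.61 ± 0.07 in naive mice (SD, n = 2), 13.32 ± 0.10 after LPS, 13.14 ± 0.19 at 100 mg/kg, 12.48 ± 0.21 at 200 mg/kg and 10.45 ± 1.19 at 300 mg/kg (n = 3 each). The 300 mg/kg arrays ranged from 9.305, below both naive arrays (9.56 and 9.65), to 11.685. Standard errors and p-values of the fit assume the same spread in all groups, so for these genes they may overstate the precision at 300 mg/kg. Camera gave an adjusted p of 1.96e-24, lost at an adjusted p = 0.477 with an estimated correlation, and fry gave 0.00129. With the actin ratio as a covariate 33 members were called, at a median of -2.71. All 36 were called whichever array was left out, with medians of -3.25 to -2.32. The group means of Ifnb1 went from 5.90 after LPS to 6.15, 7.16 and 9.14 at the 3 doses, and those of Il6 from 11.76 to 12.70, 13.85 and 14.56.

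**Figure D2:**
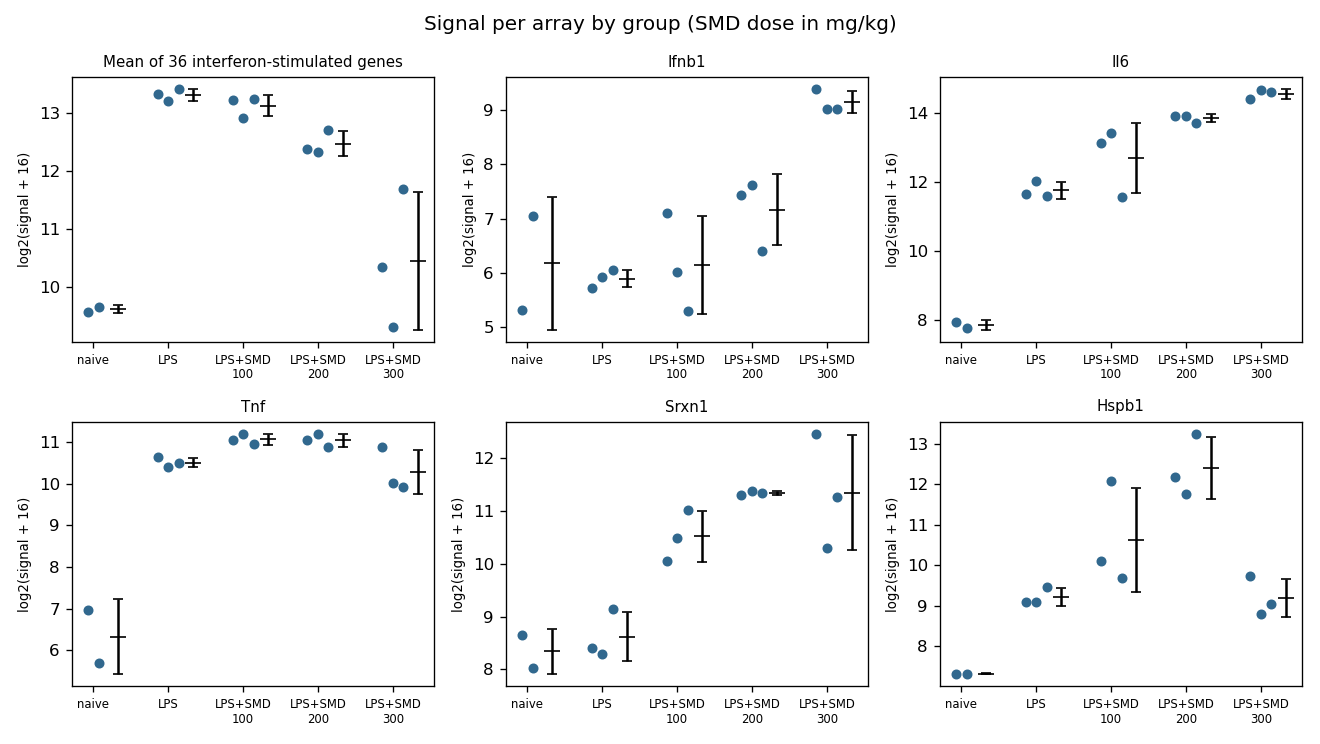
Each point is 1 array and each bar the mean ± SD of its group, as log2(signal + 16), for the mean of 36 interferon-stimulated genes and for Ifnb1, Il6, Tnf, Srxn1 and Hspb1 in naive mice, after LPS and after LPS with SMD at 100, 200 or 300 mg/kg. From LPS alone to 300 mg/kg the interferon-stimulated mean goes from 13.32 to 10.45, Ifnb1 from 5.90 to 9.14 and Il6 from 11.76 to 14.56.

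The unfolded protein and ATF4 list fell in 17 of 24 members and rose in 3 (17 and 3 adjusted over the list alone), with a median of -0.85. The one-carbon enzyme Mthfd2 stood at -1.83, the transcription factor Atf4 at -1.18 and Asns at -1.85. Camera's adjusted p of 0.000121 became an adjusted p = 0.477 with an estimated correlation, and with the actin covariate 7 fell and 1 rose. Without LPS replicate 3 or 300 mg/kg replicate 2, 1 rose. The antigen presentation and costimulation list fell in 7 of 19 members and rose in 2 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0466, adjusted p = 0.538 with an estimated correlation). Cd40 (-1.84) and Psmb8 (-1.90) fell and Cd80 (2.55) rose, the last with 0.48 and no call when all its probe sets were averaged. The list's call was lost after median scaling (0.0573), with the lowest 60% left out (0.102), no intensity trend (0.0859), only the groups compared (0.0596) and the actin (0.512, median 0.01) or Gapdh (0.0603) covariate. It was lost too without LPS replicate 3 (0.129), 100 mg/kg replicate 1 (0.057) or 3 (0.0519), 300 mg/kg replicate 2 (0.0599) or naive replicate 1 (0.05). Without LPS replicate 1 or 2, 200 mg/kg replicate 1, any 300 mg/kg array or either naive array, 1 of its members rose. Chemokines fell in 7 of 21 and rose in none (7 and 0 adjusted over the list alone, camera adjusted p = 0.0671), although after quantile normalization 3 chemokines rose. They included the interferon-inducible Cxcl9 (-3.75) and Cxcl11 (-3.55), Ccl5 (-2.16) and the monocyte attractant Ccl7 (-2.17). Cytokines rose in 3 of 19 and fell in 6 (3 and 7 adjusted over the list alone, 0.207), the latter including Il15 (-3.11) and Ebi3 (-2.04). Anti-inflammatory regulators rose in 2 of 17 and fell in 7 (2 and 7 adjusted over the list alone, 0.0671), such as Il1rn (-2.30) and Il4ra (-1.91, lost with the actin covariate), and 1 of them rose without LPS replicate 1 or 2 or 300 mg/kg replicate 1. NF-kB members rose in 3 of 15 and fell in 7 (3 and 7 adjusted over the list alone, 0.28), with Rel at 2.24 and Traf1 at -1.51. TLR4 components rose in 4 of 22 and fell in 7 (4 and 7 adjusted over the list alone, 0.349), with the kinase Ikbke at -2.86 and the LPS-response modulator Cd180 at 1.56. The MAP kinase list rose in 8 of 28 and fell in 5 (8 and 5 adjusted over the list alone, 0.534), with the phosphatase Dusp2 at -2.23 and Egr1 at 1.34. This list fell in 3 without LPS replicate 1 or 3 or 300 mg/kg replicate 2.

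NRF2 and thiol genes rose in 6 of 25 and fell in 2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.28), with Srxn1 at 2.73 ± 0.39, Gclm at 1.67 and the NRF2 inhibitor Keap1 at -2.16. For NRF2 itself, Nfe2l2, 1 probe set fell (-0.83) and another rose (3.48, adjusted p = 7.42e-06). Metal and heat-shock genes rose in 3 of 15 and fell in 2 (3 and 2 adjusted over the list alone, 0.958, median -0.02, which was 0.07 and 0.08 after quantile and median scaling, mean 0.25), with Hspa1b at 2.24 and Hspd1 at -1.08, and 1 fell without LPS replicate 1. Glucocorticoid-response genes rose in 9 of 23 and fell in 4 (9 and 4 adjusted over the list alone, 0.472), with Fgd4 at 2.99 and Cebpd at -2.48, and 5 rose without LPS replicate 1. Antimicrobial effectors rose in 1 of 21 and fell in 5 (1 and 5 adjusted over the list alone, 0.0671, 0.0385 after quantile normalization), with Ch25h, which makes 25-hydroxycholesterol, at -3.85 and Arg1 at 1.71. Prostaglandin enzymes and receptors rose in 5 of 16 and fell in 2 (6 and 4 adjusted over the list alone, 0.866, mean -0.10 with an upward test), with Ptger4 at 1.60 and Ptges at -2.41. Of these, 4 fell without 100 mg/kg replicate 3 and 1 without 300 mg/kg replicate 2. Apoptosis regulators rose in 6 of 21 and fell in 6 (6 and 8 adjusted over the list alone, 0.866, median 0.05 with a downward test), with Pmaip1 at 2.65, and 3 fell without 300 mg/kg replicate 2. Of 20 cell cycle genes 3 rose and none fell (3 and 0 adjusted over the list alone, 0.349), such as the centromere histone gene Cenpa (1.67), or 5 without 100 mg/kg replicate 1 or 3 and 1 without 300 mg/kg replicate 2. Cholesterol genes rose in 3 of 19 and fell in 1 (3 and 1 adjusted over the list alone, 0.891), with Lpl at 1.14 and Apoe at -1.56. They rose in 1 without LPS replicate 1 or 300 mg/kg replicate 3, and fell in 3 without LPS replicate 2 and in 2 without 300 mg/kg replicate 3. With the actin covariate Hspa1b, Lpl and Apoe were not called.

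Among cell markers, the macrophage list rose in 5 of 23 and fell in 4 (6 and 4 adjusted over the list alone, camera adjusted p = 0.798). Without LPS replicate 1 or 300 mg/kg replicate 2, 2 rose, and without LPS replicate 3 or 300 mg/kg replicate 2, 2 fell. Fcgr1 fell by 4.20 ± 0.32 (adjusted p = 2.62e-07), the integrin Itgam fell by 1.61, with a dose slope of 0.14 once the actin ratio was a covariate, and the growth factor Tgfb2 rose by 2.90. Vsig4 (0.59) and Timd4 (0.44) rose, while Adgre1 (0.25, adjusted p = 0.195), Csf1r (0.23), Cd68 (-0.07) and Lyz2 (-0.14) did not pass. B cell markers rose in 5 of 16 (5 adjusted over the list alone, 0.17), with Ebf1 at 1.88 and Cr2 at 1.77, and T and NK markers rose in 6 of 18 and fell in 1 (8 and 2 adjusted over the list alone, 0.28), with Thy1 at 2.36 and Gzmb at -2.58. The B cell markers that rose numbered 3 without LPS replicate 1, and 2 T and NK markers fell without LPS replicate 2 or 300 mg/kg replicate 3. Neutrophil markers rose in 5 of 15 and fell in 3 (6 and 3 adjusted over the list alone, 0.798), mast cell markers rose in 3 of 11 and fell in 2 (4 and 3 adjusted over the list alone), and 1 of 4 eosinophil markers rose, Il5ra (0.93, lost with the actin covariate). Monocyte and dendritic cell markers rose in 1 of 11 and fell in 2 (2 and 2 adjusted over the list alone), mesothelial and fibroblast markers 1 up and 1 down of 13 (1 and 1 adjusted over the list alone), and no red cell or platelet marker was called. Neutrophil markers rose in 3 without LPS replicate 1 or 2 or 300 mg/kg replicate 1. Without LPS replicate 1 or 100 mg/kg replicate 3, 2 monocyte and dendritic cell markers rose, and without LPS replicate 3, 2 eosinophil markers. Limma called 7432 probe sets, 3722 higher and 3710 lower, for 4065 genes. With the actin covariate the count was 3384.

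**Figure D3:**
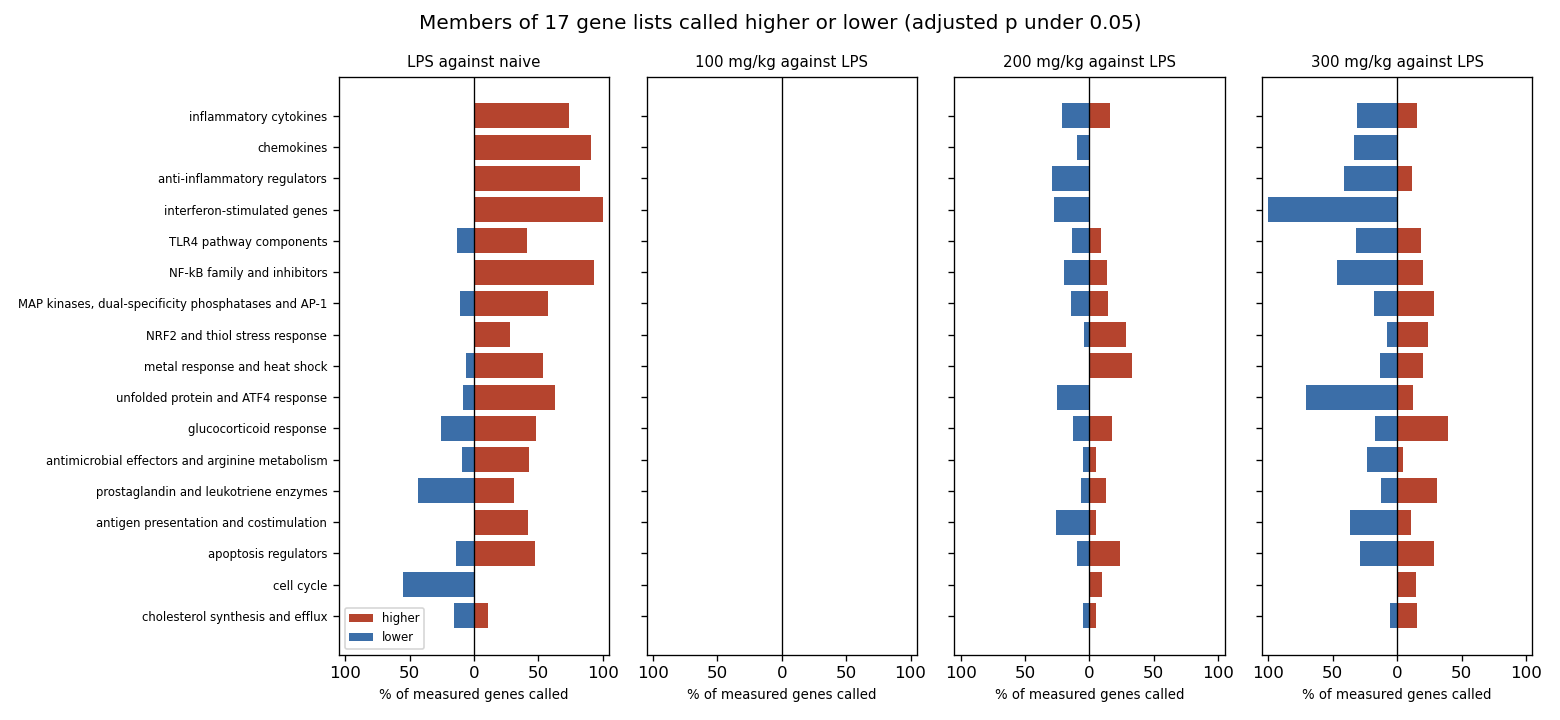
For each of 17 gene lists, bars give the percentage of measured genes called higher (red, to the right) or lower (blue, to the left) in LPS against naive and in SMD at 100, 200 and 300 mg/kg against LPS. All 36 interferon-stimulated genes were higher after LPS, and 0, 10 and 36 of them were lower at the 3 doses.

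Comparisons between doses tested whether their effects differed. From 200 to 300 mg/kg, interferon-stimulated genes fell in 34 of 36 members (35 adjusted over the list alone, median -1.97, camera adjusted p = 6.17e-34, adjusted p = 0.458 with an estimated correlation). Ifnb1 rose further (1.98, limma adjusted p = 0.0308), Cxcl10 fell (-0.93, 0.0449) and Il6 (0.71, 0.222) did not pass. Hspb1 fell by 3.21 (0.00165), so that it averaged 12.39 at 200 mg/kg and 9.18 at 300 mg/kg (log2 signal, n = 3 each). In all, 1370 probe sets were called, 545 higher and 825 lower, a share of higher calls of 39.8% that median scaling made 28.7%. Without 200 mg/kg replicate 1 the count was 732, without replicate 3 it was 492, and without 300 mg/kg replicate 2 it was 381. From 100 to 200 mg/kg, 304 probe sets were called, 213 higher and 91 lower. This count was 41 and 138 without 100 mg/kg replicates 1 and 3, 8 and 17 without 200 mg/kg replicates 1 and 2, 142 and 139 without naive replicates 1 and 2, and 456 without LPS replicate 2. Of the interferon-stimulated genes 1 fell in that step (2 adjusted over the list alone, median -0.58, camera adjusted p = 1.9e-08, adjusted p = 0.634 with an estimated correlation). From 100 to 300 mg/kg, 4794 were called, 2510 higher and 2284 lower, or 3078 without 300 mg/kg replicate 2. All 36 interferon-stimulated genes fell (36 adjusted over the list alone, median -2.62, camera adjusted p = 3.46e-30, adjusted p = 0.511 with an estimated correlation), and 5 of 16 B cell markers rose (6 adjusted over the list alone, 0.0097, adjusted p = 0.511 with an estimated correlation).

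Across the 12 arrays of LPS-challenged mice, the dose trend gave log2 slopes per 100 mg/kg. The steepest rises were those of Marveld1 (1.36 ± 0.16, SE), H1f2 (1.36 ± 0.09, limma adjusted p = 7.43e-08), Gadd45a (1.33 ± 0.11), Pxdc1 (1.26 ± 0.16) and Hnmt (1.23 ± 0.18). The steepest falls were those of Znfx1 (-1.75 ± 0.23), Iigp1 (-1.52 ± 0.24), Slfn5 (-1.51 ± 0.18), Fcgr1 (-1.42 ± 0.13, 1.08e-06) and Usp18 (-1.41 ± 0.32). For these 10 genes the group means moved in one direction at each dose step. Il6 rose by 0.96 ± 0.10 (1.94e-06), Ifnb1 by 1.08 ± 0.16 (8.56e-05), Il10 by 0.41 ± 0.10 (0.00425), Ptgs2 by 0.41 ± 0.07 (0.000323) and Hmox1 by 0.36 ± 0.13 (0.0385). The Hmox1 call was lost without LPS replicate 1 (0.0685) or 2 (0.0865), 100 mg/kg replicate 2 (0.0507), 200 mg/kg replicate 1 (0.0562) or 2 (0.0536), or 300 mg/kg replicate 1 (0.125) or 3 (0.0667). Cxcl10 (-0.41 ± 0.08) and Cd14 (-0.13 ± 0.03, 0.00885) fell. Tnf (-0.07, 0.648), Il1b (-0.11, 0.332), Tlr4 (-0.11, 0.647) and Il12b (-0.31, 0.207) did not pass. The 36 interferon-stimulated genes all fell (36 adjusted over the list alone, median -0.93, camera adjusted p = 2.16e-20, adjusted p = 0.505 with an estimated correlation). Unfolded protein and ATF4 genes fell in 14 of 24 and rose in 3 (17 and 3 adjusted over the list alone, 0.000346, adjusted p = 0.505 with an estimated correlation), and 1 rose without LPS replicate 1 or 3. Limma called 7392 probe sets, 3671 with a rising and 3721 with a falling slope. The actin ratio rose over the same doses, and with it as a covariate 2771 were called, with Hnmt (0.57, adjusted p = 0.113), Il10 (0.34, 0.184), Ptgs2 (0.25, 0.139) and Cd14 (-0.13, 0.121) no longer among them.

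The SMD effects were also set against the LPS effect, which asked whether LPS-responsive genes moved back towards the naive level. Among genes raised by LPS, 1496 probe sets were lower at 300 mg/kg, against 380.7 for independent lists, and 2296 lowered by LPS were higher (625.3). Interferon-stimulated genes such as Usp18 and Ifit3 belonged to the first kind, and Marveld1 and Mdm1 to the second. Il6 was an exception, raised by LPS (3.90) and again by SMD (2.80), 1 of 133 probe sets raised in both, against 382 for independent lists. At 200 mg/kg the corresponding overlaps were 603 (177.3) and 1137 (303.1). Over the 7313 probe sets called in LPS against naive, 68.4%, 76.9% and 84.6% had the opposite sign at 100, 200 and 300 mg/kg. Slopes of the SMD change on the LPS change were -0.10, -0.24 and -0.49, and covariances -0.319, -0.767 and -1.61. Because both comparisons hold the LPS arrays, simulated unchanged groups gave 59.0%, 59.0% and 58.9%, a slope of -0.06 and a covariance of -0.203. That simulation lets the genes vary independently. After median scaling the shares were 60.9%, 67.8% and 78.4%, against simulated means of 59.3%, 59.1% and 59%. At 100 mg/kg the highest of 20 simulated draws was then 60.7%, so that share barely exceeded unchanged groups. Between doses, 1603 probe sets were higher and 1363 lower at both 200 and 300 mg/kg, against 248.5 and 237.2 for independent lists. The log2 changes correlated across genes, which are not independent replicates, at r = 0.746 between 200 and 300 mg/kg, 0.618 between 100 and 200 and 0.537 between 100 and 300, where shared LPS arrays alone gave 0.5. The covariances were 0.532, 0.248 and 0.277 against a simulated 0.112. The 3 LPS arrays are too few to be split into separate controls, so part of any excess may come from sharing them.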

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

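In this part, all weighing of RNA quality, harvest time, macrophage share, Ifnb1 and exchanged labels rests on tests chosen after the results were seen, while the counts over other splits of the arrays were set beforehand.

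The control probe sets, which no comparison used, gave a signal above the controls. The actin 3'/5' ratio averaged 14 at 300 mg/kg SMD against 3.32 after LPS alone, and the Gapdh ratio 92 against 7.82 in naive mice, though after LPS alone it was 37.8 ± 47.4 (SD) with LPS replicate 2 itself at 92. Effects against LPS differed between doses, by limma's test of the difference, for 304 probe sets between 100 and 200 mg/kg, 1370 between 200 and 300 mg/kg and 4794 between 100 and 300 mg/kg. Some genes called at 200 mg/kg were called in the other direction from 200 to 300 mg/kg, 17 probe sets down after up and 30 up after down, fewer than the 55.1 and 34.9 that independent lists give. Both comparisons share the 200 mg/kg arrays, which favours opposite signs. From 200 to 300 mg/kg, the log2 change of Hspb1 was -3.21 (adjusted p = 0.00165) after a rise of 3.18 at 200 mg/kg, and that of the chaperone gene Hsph1 was -1.40 (0.0132) after 1.72. The T cell costimulator gene Tnfsf9 changed by -1.18 (0.00643) after 0.96, glutathione reductase Gsr by -0.59 (0.0347) after 0.75, and Zfp36, whose product destabilises cytokine mRNA, by 0.51 (0.0433) after -0.49.

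All 36 interferon-stimulated genes fell at 300 mg/kg while Ifnb1 rose. With the log2 actin ratio as a covariate the median fall was still -2.71 against -2.77, which argues against a linear effect of RNA quality as its whole cause, and against the 100 mg/kg arrays, which share the stated harvest time of 2.0 h, it was -2.62. Resident macrophage markers did not fall together (lower quartile -0.105), which argues against a loss of macrophages as large as that fall. LPS alone had changed several of them (4 of 23 rose and 9 fell), so they do not measure cell number directly. Ifnb1 at harvest was higher, not lower, than after LPS alone, by 3.24 (9.14 ± 0.21 against 5.90 ± 0.16, SD, n = 3 each). Its level after LPS alone was near the naive one (6.18) and the filter cut of 5.64, so a fall could hardly have been called. One hypothesis left is that the highest dose may act on the response to interferon or on interferon made before harvest, which no value here tests, and a delayed response is weighed among the other observations.

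The number of calls at 200 and 300 mg/kg depended on the actin ratio. With it as a covariate, the log2 changes of the called probe sets had a slope of 0.677 on the unadjusted ones at 200 mg/kg (0.635 to 0.737 when single arrays were left out) and of 0.783 at 300 mg/kg (0.714 to 0.841), with the same sign in 99.4% and 96.4%. Calls fell from 3532 to 407 and from 7432 to 3384, as changes shrank and the median standard error grew from 0.256 to 0.297 and from 0.262 to 0.353. RNA quality and SMD dose rise together, so a part of these changes that follows RNA quality cannot be told apart from an effect of the dose. Genes such as Srxn1, Il6 and Slc30a1 were called at both doses with either ratio as a covariate.

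Among the LPS and 100 mg/kg arrays, 1 other split of the 6 arrays, LPS replicates 1 and 3 with 100 mg/kg replicate 3 against LPS replicate 2 with 100 mg/kg replicates 1 and 2, called 2860 probe sets where the real split called 0, which points to a structure of the samples. For exchanged labels of LPS replicate 2 and 100 mg/kg replicate 3 the values go both ways: 6 NRF2 and thiol genes called higher at 200 mg/kg (Gclm, Srxn1, Slc7a11, Gsr, Abcc1 and Cat) lay above LPS replicate 2 in 100 mg/kg replicate 3 by 1.16 ± 0.36 log2 units (SE over the 6 genes, 1 array per side), 6 of 6 higher, but of all 2483 genes called at 200 mg/kg without LPS replicate 2 27.4% differed between these 2 arrays in the direction of their change at 200 mg/kg. Il6 stood at 11.56 in 100 mg/kg replicate 3, just below the LPS arrays (11.59 to 12.03, the highest in LPS replicate 2). The other 100 mg/kg arrays stood higher (13.12 and 13.42). An exchange can therefore not be told apart from other causes. The split follows the actin ratio, with 1.92, 2.17 and 2.72 on one side and 5.86, 4.33 and 11.6 on the other, and its log2 differences correlated across probe sets at r = 0.263 with the actin slope within the other groups (permutation p = 0.0833, 72 permutations). Uneven RNA quality may therefore contribute but cannot be told apart from another structure with so few arrays.

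For the comparisons of 3 arrays with 3, 10 splits exist, too few for a share under 0.05. At 100 mg/kg against LPS all 10 splits called at least the real 0, the highest being 2860. The real split alone, 1 of 10, reached its count in each of the other comparisons. The real count and the highest of the other splits were 3532 and 0 at 200 mg/kg against LPS, 7432 and 1 at 300 mg/kg against LPS, 304 and 2 for 200 against 100 mg/kg, 1370 and 1 for 300 against 200 mg/kg, and 4794 and 0 for 300 against 100 mg/kg. For the dose trend, 1 of 100 assignments of the doses to the 12 arrays, the real one, reached 7392 calls, and the highest other called 724. That share of 1 in 100 is the smallest the test can give, so chance assignment is unlikely but not excluded. The actin ratio rises with the dose, so the test does not tell an effect of dose from one of RNA quality.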

How the results depend on the processing

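The fits with the actin or Gapdh 3'/5' ratio as a covariate and those on arrays with an actin ratio from 4 to 12 were chosen after the data were seen. Over 493 results for named genes, the settings chosen beforehand gave 12310 values. Of these 11920 kept the side of the threshold, and the direction where called, 344 lost the call and 39 gained one. A further 7 changed sign with a call before or after. Changes of sign without a call in either fit are counted among the 11920. The later settings, counted in the same way, gave 1372 values, with 1022 the same, 340 lost, 6 gained and 4 of the other sign. Among them, the fits on arrays with an actin ratio from 4 to 12 say nothing about stability against LPS or 300 mg/kg, as these groups keep 1 array each. Dim probe sets limit the rest, since those under a signal of about 33.9 were not tested.

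Averaging the probe sets of a gene tests fewer items. In brackets stand the probe sets called in the main fit and the genes called there by their highest-mean probe set. Averaging gave 3771 calls for LPS against naive (7313 and 4164), 1375 at 200 mg/kg against LPS (3532 and 1916) and 3529 at 300 mg/kg (7432 and 4065). Between doses it gave 66 for 200 against 100 mg/kg (304 and 170), 644 for 300 against 200 mg/kg (1370 and 859) and 2252 for 300 against 100 mg/kg (4794 and 2756). For the dose trend it gave 3497 (7392 and 3996). Without the intensity trend the counts were 1762 at 200 mg/kg, 24 for 200 against 100 and 375 for 300 against 200 mg/kg. Array weights gave 301 at 100 mg/kg, 5597 at 200 mg/kg and 691 for 200 against 100 mg/kg, where only the compared groups gave 149. The actin covariate gave 407 at 200 mg/kg, 3384 at 300 mg/kg, 2284 for 300 against 200 mg/kg and 2771 for the trend, and the Gapdh covariate 743 at 200 mg/kg and 111 for 200 against 100 mg/kg. Arrays with an actin ratio from 4 to 12, with 1 LPS array (replicate 2) and 1 at 300 mg/kg (replicate 1), gave 2, 408 and 2322 at 100, 200 and 300 mg/kg against LPS, 692 for 300 against 200 mg/kg, 2283 for 300 against 100 mg/kg and 2011 for the trend. Apart from fewer items or arrays, the cause was not tested. Leaving out single arrays gave 4362 to 7783 calls for LPS against naive, 0 to 470 at 100 mg/kg, 1264 to 4605 at 200 mg/kg, 5460 to 7949 at 300 mg/kg, 8 to 456 for 200 against 100, 381 to 1738 for 300 against 200 and 3078 to 5078 for 300 against 100 mg/kg, and 5946 to 7600 for the trend. Averaged probe sets turned the sign of Nfkbib (0.29), Mapk14 (-0.017) and Kit (-0.57) at 200 mg/kg, of Nfe2l2 at 300 mg/kg (1.33) and in the trend (0.49), and of Mapk14 in the trend (-0.013). In Nfkbib, Kit and Nfe2l2 this goes with probe sets called in opposite directions. Median scaling turned Alox15 in LPS against naive (0.046). The actin covariate turned Itgam (0.16) and Tpsb2 (0.10) at 200 mg/kg and Itgam (0.14) and Irf4 (0.048) in the trend. For these the cause was not tested.

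The replicate numbers are shared between groups, but nothing says that they mark a day or litter. Deviations of same-numbered arrays correlated at -0.127 to 0.185 (26 pairs, median 0.0157), against -0.265 to 0.223 for different numbers (52 pairs, median -0.00992). These values show no pairing by number, but with 2 or 3 arrays per group they cannot exclude it. With the replicate number as a block the counts were 6696 for LPS against naive, 0, 3544 and 7362 at 100, 200 and 300 mg/kg against LPS, 312, 1347 and 4726 between doses and 7188 for the trend.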

Other observations

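The list tests in this part were chosen after the results were seen. They covered 72 gene families defined by the start of their symbols and 3 further lists, with adjustment over these 75. Calls of single probe sets, except those with the actin covariate, come from the comparisons set beforehand, adjusted over all tested probe sets. Single genes outside the rule for named genes were picked after their values were seen.

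Gene groups outside the lists of the main comparisons also moved at 300 mg/kg against LPS. Mitochondrial ribosomal protein genes of the large subunit (Mrpl) fell in 24 of 47 measured members and rose in 3, with a median of -0.56 (camera adjusted p = 0.000109, adjusted p = 0.121 with an estimated correlation). With the actin ratio as a covariate 12 fell and the median was -0.24. RNA polymerase subunit genes (Polr) fell in 10 of 25 (median -0.48, 0.00581), the DEAD-box RNA helicase genes (Ddx) fell in 15 of 35 and rose in 4 (-0.50, 0.00888), and Mediator subunit genes (Med) fell in 11 of 30 and rose in 3 (-0.53, 0.0109). With an estimated correlation their adjusted p values were 0.304, 0.282 and 0.282, and with the actin covariate 6, 9 and 4 fell. In the other direction, centrosomal protein genes (Cep) rose in 13 of 34 and fell in none (median 0.80, 0.0138, adjusted p = 0.332 with an estimated correlation), or in 5 with the actin covariate. Cep genes had fallen in 16 members after LPS alone and Ddx genes had risen in 14. Quantile normalization and median scaling kept the sign of each of these medians at 300 mg/kg. No family or list tested here was called at 300 mg/kg with an estimated correlation.

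Targets of FOXO transcription factors, which are active when growth factor signalling is low, rose in 10 of 19 measured genes and fell in 1 at 300 mg/kg (median 0.82, camera adjusted p = 0.00888, adjusted p = 0.159 with an estimated correlation), and in 9 with the actin covariate (median 0.77). At 200 mg/kg also 10 rose and 1 fell (median 0.77, camera adjusted p = 0.00574, adjusted p = 0.126 with an estimated correlation), but 1 rose with the actin covariate (median 0.61). Among them were Sesn1 (2.41), Ccng2 (2.31), the insulin receptor gene Insr (2.12) and Pink1 (1.73). LPS alone had lowered Sesn1 (-2.51), Ccng2 (-1.96) and Insr (-3.18), while of the FOXO target genes as a list 4 rose and 8 fell (median -0.55, camera adjusted p = 0.404, adjusted p = 0.521 with an estimated correlation), or 6 and 4 after median scaling (median -0.12). At 300 mg/kg, targets of p53 went both ways, with 8 of 21 up and 5 down (median 0.36, camera adjusted p = 0.322), such as Gadd45a (3.82) and Mdm2 (0.83) against Aen (-2.07). Between 200 and 300 mg/kg, 17 probe sets that were higher at 200 mg/kg than after LPS fell (55.1 for independent lists), such as the one of the vasoactive peptide adrenomedullin, Adm (1.58, then -1.13), and 30 that were lower rose (34.9 for independent lists), such as that of the complement C3a receptor gene C3ar1 (-0.91, then 1.61).

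One hypothesis was that the response to LPS ran later in mice given 300 mg/kg SMD, so that early LPS-response genes might still be high at harvest. The list of 27 such genes, 18 of which are also in lists tested before, had a median change of 0.221 with 8 up and 3 down (camera adjusted p = 0.198). Maff (2.55), Phlda1 (2.53) and Klf6 (1.84) rose, while Tnfaip3 (0.22), Cxcl1 (0.25), Cxcl2 (0.25), Dusp1 (0.09) and Nfkbia (-0.09) did not pass. These values leave the hypothesis open, and with a single stated harvest time a delay cannot be told apart from a changed response.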
